A study of Homo sapiens with 15 samples.

How the data were processed

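RNA was measured by poly-A sequencing of primary human renal proximal tubule epithelial cells, in 15 libraries that form 5 groups of 3. Per the labels, libraries were read as 150-base pairs, and whether the kit keeps strand is not stated. Antisense and overlapping genes therefore cannot be told apart. Per the submitters' processing notes, DRAGEN and GRCh38 were used; their versions and the annotation release are not given in the sources used here. Per the file headers, each deposited file lists genes with lengths, TPM and estimated counts of reads. Each file held 60671 genes. Of the estimated counts the authors deposited, 12.6% of values were not whole, and they were rounded to whole numbers for the count tests. TPM as deposited by the authors was used only for the level of PLIN2.

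Gene symbols were matched by identifier for 60401 genes, and coordinates come from GENCODE release 29 on GRCh38, which held 58453 of them. Estimated reads per library ran from 14387294 to 46595414. The main test was edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3 on all 15 libraries, with group means, TMM factors and the filter filterByExpr by group. The fit had 10 residual degrees of freedom and a common biological coefficient of variation of 0.11. The filter left 17849 genes, which took at least 99.9% of the reads of each library; 42822 genes were not tested. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Adjusted p-values of genes throughout are from this edgeR test, fold changes are on the log2 scale with their standard error, and CPM values are group means with the SD over 3 libraries.

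The comparisons were oleate against no load in control cells, PLIN2 siRNA against control siRNA at the end of the load and 2 days later, control cells at 2 days against each earlier control group, and the difference between the siRNA effects at the 2 times. No group had the PLIN2 siRNA without oleate, no siRNA at all, or 2 days of culture without oleate. These designs, 36 gene lists with 735 genes, 24 fixed genes and the alternatives were set before the data were examined. PLIN2 was in no list. Lists with at least 5 tested members, 33 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and the rotation test fry were alternatives. Calls were also adjusted over the members of each list alone.

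Genes were named by rule. In each comparison these were the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and, between 2 groups, no overlap of libraries. The 24 fixed genes and the 4 members with the smallest adjusted p of each described list were added. Unnamed loci, readthrough genes and pseudogenes were skipped among the largest changes. Some genes that this rule names are not reported here. Genes with near-identical copies can share reads, and mitochondrially encoded genes have nuclear copies, so their values are uncertain.

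Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library totals alone, no filter, a filter of 5 CPM in 3 libraries, effective gene length as an offset, mitochondrially encoded genes left out, only the groups compared, a replicate block, an adjusted p of 0.01, a test against a fold change of 1.5, and each library left out in turn. Leaving out replicate 3 of the 2-day PLIN2 siRNA group in every comparison was added after the data were seen. Overlaps between comparisons that share controls were set beside 100 simulations of unchanged groups, with a spread estimated from all 15 libraries. A regression of fold changes on 7-base words in 3' UTRs, with UTR length and base composition, used genes of at least 5 CPM and words in at least 50 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

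The tests were checked on simulated counts with 200 changed genes, 67 at 1.5-fold, 67 at 2-fold and 66 at 4-fold. For oleate at 6 h, over 17540 genes, 56.7%, 85.1% and 100% were recovered, and 10.6% of calls were false. For the PLIN2 siRNA at 6 h, over 17536 genes, recovery was 55.2%, 89.6% and 100%, with 4.7% false. For 2 days against unloaded, over 17569 genes, it was 58.2%, 94% and 100%, with 3.4% false. For 2 days against the end of the load, over 17535 genes, it was 62.7%, 83.6% and 98.5%, with 5.8% false. For the PLIN2 siRNA at 2 days, over 17528 genes, it was 64.2%, 89.6% and 98.5%, with 5.1% false. For the difference of siRNA effects, over 17520 genes, it was 37.3%, 67.2% and 93.9%, with 2.9% false. Each simulated gene varied independently of the others. Shifts of many genes together in a library were not simulated, such as the trend over GC content in replicate 3 of the 2-day PLIN2 siRNA group. The shares of false calls may therefore not hold for the real counts.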

Results

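The data are RNA-seq read estimates from primary human renal proximal tubule epithelial cells, the cells that line the kidney tubule segment where most filtered solutes are reabsorbed. Cells received a non-targeting control siRNA or an siRNA against PLIN2, which encodes a protein that coats lipid droplets. They were then left without a lipid load or given oleate bound to albumin for 6 h, and were collected at the end of the load or 2 days later. The 5 groups of 3 libraries were control siRNA without oleate (unloaded), control siRNA after 6 h of oleate, PLIN2 siRNA after 6 h of oleate, and each siRNA 2 days after the load. Estimated reads assigned to genes ran from 14387294 to 46595414 per library, and 1 CPM therefore stood for 14.4 to 46.6 reads. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

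PLIN2 was measured first, because it is the siRNA target. PLIN2 (ENSG00000147872) lies on chromosome 9 from 19108375 to 19149290 in GRCh38. Its deposited TPM averaged 198 ± 3.4 (SD, n = 3 here and below) in unloaded cells and 1100 ± 49 after 6 h of oleate with the control siRNA. With the PLIN2 siRNA it was 147 ± 15 after 6 h of oleate. At 2 days it was 138 ± 0.56 with the control siRNA and 17.3 ± 4.5 with the PLIN2 siRNA. PLIN2 rose 5.67-fold with oleate (log2 fold change 2.50 ± 0.07 SE, adjusted p = 4.7e-10). The siRNA left 12.5% of the control level at 6 h (log2 fold change -3.00 ± 0.08, adjusted p = 5.6e-11) and 13.3% at 2 days (-2.91 ± 0.08, adjusted p = 1.2e-10). In control cells PLIN2 at 2 days was 7.6-fold below its level at the end of the load (log2 fold change -2.93, adjusted p = 1.2e-11). It was also below the unloaded level (-0.42, adjusted p = 3e-04), a call that was lost when tested against a fold change of 1.5. An exact permutation test of TPM gave p = 0.1 in each comparison, the smallest that 3 against 3 libraries allow.

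**Figure D1:**
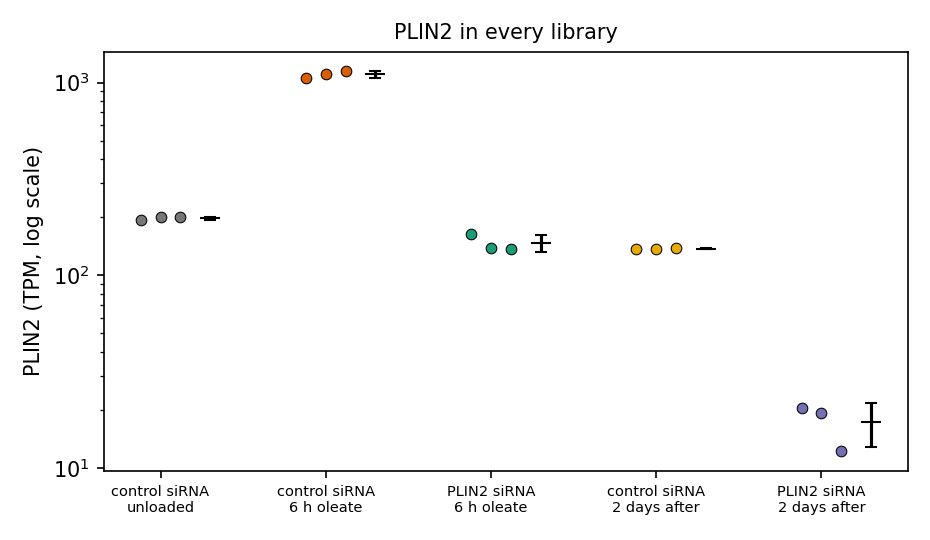
PLIN2 level (TPM, log axis) in each of the 15 libraries, with 3 points per group and a bar at the mean with its SD. Group means run from 17.3 TPM with the PLIN2 siRNA 2 days after the load to 1100 TPM with the control siRNA after 6 h of oleate.

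The first principal component took 46.5% of the variance and separated the 2-day libraries from the rest. Replicate 3 of the 2-day PLIN2 siRNA group stood apart from its group. Genes of the mitochondrial genome and its ribosomal RNAs took 19.76% of its reads, against 8.51% in each of the other 2 libraries and 3.98% to 6.38% in the other 4 groups. Its read-weighted GC content was 48.54%, against 50.89% and 50.87% in the other 2 libraries and 51.37% to 51.68% in the other 4 groups. The library enters the estimate of spread shared by all comparisons, so totals of called genes are also given without it, as are list counts whose larger direction moved by over 1.5 times, a choice made after seeing the data.

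The first comparison asked what 6 h of oleate changed in cells with the control siRNA. Genes of fatty acid oxidation and genes induced by interferon rose. PDK4 (chromosome 7, 95583499 to 95596491), a kinase that inhibits pyruvate dehydrogenase, rose 7.67-fold from 7.6 ± 0.282 to 58.6 ± 1.01 CPM (adjusted p = 9.5e-07). CPT1A, which starts the import of long-chain fatty acids into mitochondria, rose 2.07-fold from 52.2 ± 1.81 to 108 ± 2.01 CPM (adjusted p = 1.1e-07). Of 17849 genes tested, 191 rose and 85 fell. Among targets of the PPAR fatty acid receptors, 9 of 21 rose and 12 were not called; adjusted over the list alone, 12 rose and 2 fell (list adjusted p = 5.2e-16, and 0.00011 with an estimated correlation). SLC25A20, the mitochondrial acylcarnitine carrier, rose by 0.76 on the log2 scale. ANGPTL4, an inhibitor of lipoprotein lipase, rose from 971 ± 123 to 1910 ± 63.5 CPM, with an adjusted p of 0.013. Its adjusted p was 0.075 and 0.086 without unloaded replicate 1 or 2, and 0.061 and 0.062 without oleate replicate 2 or 3. In mitochondrial beta-oxidation, 5 of 21 genes rose and 16 were not called, with 5 adjusted over the list alone (adjusted p = 0.0044 with an estimated correlation). CD36, a fatty acid transporter, had at most 6 reads in any library and was not tested.

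Of 29 interferon-induced genes, 27 rose and 2 were not called, and all 29 rose adjusted over the list alone (median log2 fold change 2.03). The list's adjusted p was 0.011 with an estimated correlation, and 0.087 without replicate 3 of the 2-day PLIN2 siRNA group. MX1, an antiviral GTPase, rose from 22.8 ± 4.41 to 143 ± 61.4 CPM, IFIT1 from 10.3 ± 2.07 to 71.1 ± 36.4 CPM and ISG15 from 30.8 ± 4.79 to 128 ± 47.3 CPM. OAS2 and IFI27 rose by 2.97 and 2.28 on the log2 scale. The mean log2 CPM of the list was 2.72 ± 0.09 in unloaded cells and 4.52 ± 0.55 after oleate, so the oleate libraries differed more among themselves than the unloaded ones. Of 25 genes of cholesterol synthesis and uptake, 3 rose and 22 were not called, with 10 adjusted over the list alone (adjusted p = 0.021 with an estimated correlation, and 0.069 without the same library). FDFT1, which makes squalene, rose by 0.34. In the NF-kB inflammation list, 5 of 28 rose, with 8 adjusted over the list alone (adjusted p = 0.063 with an estimated correlation), among them TNFAIP3 at 0.56, whose adjusted p was 0.15 with gene length as an offset.

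In the TGF-beta and matrix list, 3 of 29 genes rose, both over all genes and adjusted over the list alone (adjusted p = 0.3 with an estimated correlation): CCN1 and THBS1, both at 0.66, and CCN2 at 0.49. In lipid droplet coat and storage, 2 of 24 genes rose, also adjusted over the list alone (list adjusted p = 0.47): HILPDA at 0.53 (adjusted p = 0.072 with gene length as an offset), and PLIN4 at 0.92. The PLIN4 call was lost in 9 of 17 other settings, stricter thresholds not counted, among them each of the 6 without 1 library of the groups compared, where its adjusted p ran from 0.078 to 0.16. Of 13 mitochondrially encoded genes, 0 were called with all 15 libraries, and their median was -0.34 (adjusted p = 0.011, 0.68 with an estimated correlation, and 0.06 without oleate replicate 3). SMAD3, a transducer of TGF-beta signals, fell from 72.6 ± 3 to 37.7 ± 1.37 CPM (adjusted p = 1.7e-06, and 0.18 with gene length as an offset). NRIP1, a nuclear receptor corepressor, fell from 125 ± 4.18 to 71 ± 1.06 CPM. Other large falls were LHX1 at -0.93, RAPGEF3 at -0.89 and MEG3 at -0.98. The total of 276 called genes became 1792 without replicate 3 of the 2-day PLIN2 siRNA group. In that setting 19 cholesterol genes, 8 of beta-oxidation, 11 of inflammation and 5 of the matrix list rose, 1 of inflammation and 2 of the matrix list fell, and 11 of the 13 mitochondrially encoded genes fell (list adjusted p = 7.4e-11, and 0.18 with an estimated correlation). Without 1 of the 6 libraries compared it was 157, 118 and 160 (unloaded replicates 1, 2 and 3) and 206, 133 and 133 (oleate replicates 1, 2 and 3).

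**Figure D2:**
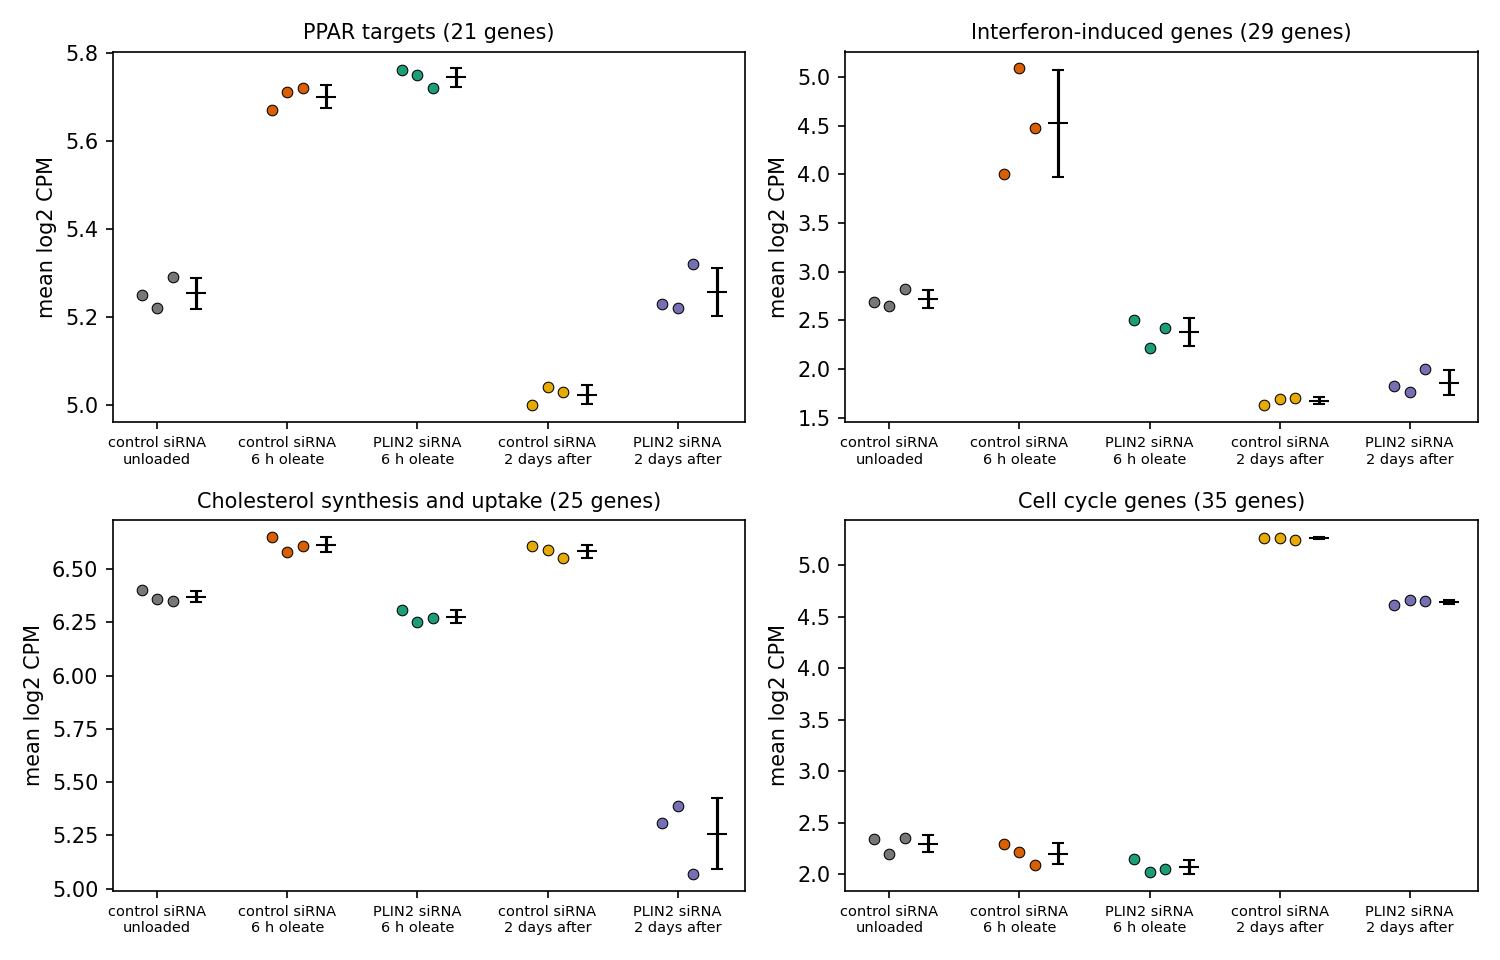
Mean log2 CPM of 4 gene lists in each library, with 3 points per group and a bar at the mean with its SD. The interferon list averages 4.52 after 6 h of oleate with the control siRNA and at most 2.72 in the other 4 groups; the cell cycle list averages 5.26 and 4.64 in the 2-day groups and at most 2.3 in the rest.

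The second comparison asked what the PLIN2 siRNA changed at the end of the load. All 29 interferon-induced genes fell with the PLIN2 siRNA, also adjusted over the list alone (median log2 fold change -2.44; list adjusted p = 1.9e-39, and 0.064 with an estimated correlation). MX1 was at 14.8 ± 3.23 CPM against 143 ± 61.4 in control cells, a log2 fold change of -3.27 ± 0.29 (adjusted p = 1.2e-05). OAS1, OAS2 and OAS3 fell (log2 fold changes -2.58, -3.62 and -2.41), as did IFI6 (-2.68). The mean log2 CPM of the list was 2.38 ± 0.15, against 2.72 ± 0.09 in unloaded control cells.

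Of 25 cholesterol genes, 13 fell and 12 were not called, with 16 adjusted over the list alone (median -0.35; adjusted p = 0.064 with an estimated correlation). HMGCS1, an early enzyme of cholesterol synthesis, fell from 143 ± 6.78 to 83.4 ± 0.649 CPM. STARD4 and SQLE fell (log2 fold changes -0.67 and -0.54). In fatty acid synthesis, 5 of 19 genes fell and 1 rose, the same numbers adjusted over the list alone (adjusted p = 0.16 with an estimated correlation). SCD, which makes oleate from stearate, fell from 491 ± 14 to 290 ± 8.68 CPM, and FADS1 and ME1 fell (log2 fold changes -0.46 and -0.43). The glycolysis and HIF list had 9 of 28 genes lower, with 16 adjusted over the list alone (adjusted p = 0.16 with an estimated correlation). PFKFB4, EGLN3 and HK2 fell (log2 fold changes -0.82, -0.48 and -0.35).

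In the ATF4 list of the integrated stress response, 10 of 27 genes rose and 1 fell, with 11 and 2 adjusted over the list alone (adjusted p = 0.16 with an estimated correlation). CTH rose by 0.63, ATF4 by 0.39 and DDIT3 from 21 ± 1.2 to 26.8 ± 0.0832 CPM. In the ER chaperone list, 6 of 22 genes fell, with 9 adjusted over the list alone (adjusted p = 0.15 with an estimated correlation); CALR and PDIA3 each fell by 0.59. In the NRF2 list, 5 of 23 fell and 2 rose, with 10 and 3 adjusted over the list alone (adjusted p = 0.15 with an estimated correlation). AKR1C1 fell by 0.70, a value that is uncertain because its sequence is close to that of AKR1C2. In the heat shock list, 4 of 15 fell, with 7 adjusted over the list alone (adjusted p = 0.16 with an estimated correlation), among them HSPB1 at -0.36.

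Fatty acid oxidation genes that oleate had raised gave these values with the PLIN2 siRNA. PDK4 was at 66.8 ± 3.57 CPM against 58.6 ± 1.01 (log2 fold change 0.19 ± 0.15, adjusted p = 0.53). Without replicate 3 of the 2-day PLIN2 siRNA group PDK4 was called, at 0.2 ± 0.05 (adjusted p = 0.0031). CPT1A rose further by 0.23 (adjusted p = 0.0074). Among PPAR targets, 6 of 21 rose and 2 fell, the same numbers adjusted over the list alone (list adjusted p = 0.097). The largest rises were SMIM32, from 1.4 ± 0.323 to 5.11 ± 0.475 CPM, VAV3 at 1.05 and ELF3, an epithelial transcription factor, at 1.02. Of markers of other cell types, those of fibroblasts summed to 421 to 434 CPM with the PLIN2 siRNA and 372 to 392 CPM in control cells. THY1 was at 0.21 (adjusted p = 0.14), the collecting duct marker SCNN1A at -0.29 (0.051) and the immune marker CD68 at -0.30 (0.29), and these adjusted p-values were 0.00026, 0.00012 and 0.0032 without replicate 3 of the 2-day PLIN2 siRNA group. In all, 660 genes rose and 1047 fell. With library totals alone the split was 1020 higher and 738 lower. The 1707 called genes became 6010 without replicate 3 of the 2-day PLIN2 siRNA group. In that setting 21 cholesterol genes, 12 of fatty acid synthesis, 23 of glycolysis and HIF, 16 ER chaperones, 14 of the NRF2 list and 12 of the heat shock list fell. In the ATF4 list 20 rose and 2 fell, in the NRF2 list 4 rose, and of PPAR targets 8 rose and 4 fell. Without 1 of the 6 libraries compared they were 1153, 961 and 1048 (control replicates 1, 2 and 3) and 1036, 985 and 997 (PLIN2 siRNA replicates 1, 2 and 3).

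The third comparison set control cells 2 days after the load against unloaded cells. No unloaded cells were collected at 2 days, so culture time and oleate cannot be separated in it. Genes of cell division rose and inflammatory genes fell. MKI67, a marker of dividing cells, rose from 2.73 ± 0.212 to 137 ± 2.7 CPM, and DLGAP5, a spindle protein, from 0.411 ± 0.2 to 22.6 ± 0.721 CPM. Of 35 cell cycle genes, 32 rose and 3 were not called, also adjusted over the list alone (median 3.45; adjusted p = 0.0031 with an estimated correlation, and 0.053 without replicate 3 of the 2-day PLIN2 siRNA group). CCNA2, CCNB2, FOXM1 and RRM2 rose by 4.73, 4.42, 3.59 and 3.61. Of 22 p53 targets, 14 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.078 with an estimated correlation); BTG2 rose by 2.04 and TP53INP1 by 1.27. Fatty acid synthesis had 10 of 19 genes higher and 0 lower, also adjusted over the list alone (adjusted p = 0.3 with an estimated correlation), with SCD at 0.83 and ELOVL6 at 1.25.

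Of 28 inflammation genes, 21 fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.022 with an estimated correlation, and 0.053 without that library). CXCL8, a neutrophil chemokine, fell from 5.16 ± 0.417 to 1.07 ± 0.168 CPM, and CXCL5 and CXCL1 fell (log2 fold changes -3.43 and -2.68). In the ER chaperone list, 16 of 22 fell, also adjusted over the list alone (adjusted p = 0.084 with an estimated correlation); HSPA5, the main chaperone of the ER, fell from 2140 ± 222 to 714 ± 3.91 CPM. In the ATF4 list, 15 of 27 fell and 2 rose, with 16 and 2 adjusted over the list alone (adjusted p = 0.21 with an estimated correlation), with STC2 at -1.96 and DDIT3 at -1.02. Of 29 interferon-induced genes, 16 fell, with 19 adjusted over the list alone (adjusted p = 0.51 with an estimated correlation). Of 29 TGF-beta and matrix genes, 17 fell and 6 rose, with 17 and 7 adjusted over the list alone (adjusted p = 0.14 with an estimated correlation); MMP2 was at -1.26.

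Of 32 proximal tubule genes, 10 rose and 17 fell, with 10 and 18 adjusted over the list alone (list adjusted p = 0.12). SLC34A1, the sodium-phosphate transporter of this segment, fell from 11.8 ± 0.854 to 0.487 ± 0.212 CPM, and SLC22A2 fell by 1.48, while CA12 rose by 1.98. PPAR targets had 4 of 21 genes higher and 10 lower, the same adjusted over the list alone (list adjusted p = 0.065). ANGPTL4 fell from 971 ± 123 to 243 ± 3.1 CPM and CPT1A fell by 0.50. Markers of other cell types also moved in this comparison. Of the 3 collecting duct markers tested, SCNN1A and AQP3 were at 0.57 and 0.47 and HSD11B2 at -0.85. The AQP3 call was lost without any 1 of the 6 libraries compared except unloaded replicate 2, with an adjusted p from 0.06 to 0.12, and with library totals alone (0.061). The fibroblast markers DCN and THY1 were at 1.21 and -0.91, and the immune marker CD14 rose by 0.97. Of the 3 immune markers tested, only CD14 was called. CD68 was at 0.33 (adjusted p = 0.11, and 0.0012 without replicate 3 of the 2-day PLIN2 siRNA group). Of the 10 immune markers, 7 had at most 3 reads in any library. In all, 3628 genes rose and 3590 fell, a total of 7218 that became 10642 without replicate 3 of the 2-day PLIN2 siRNA group. In that setting all 13 mitochondrially encoded genes rose, against 0 called with all libraries, and members against the direction of their list numbered 3 of fatty acid synthesis, 5 of p53 targets, 5 of the ATF4 list and 2 ER chaperones.

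The fourth comparison set control cells 2 days after the load against control cells at its end. Culture time and withdrawal of the load cannot be separated in it either. PDK4, CPT1A and SLC25A20, which oleate had raised, fell. The log2 fold change was -3.59 for PDK4 (adjusted p = 2.2e-09), -1.55 for CPT1A (adjusted p = 4.8e-11) and -1.16 for SLC25A20. Of 21 PPAR targets, 15 fell and 3 rose, with 15 and 4 adjusted over the list alone (adjusted p = 0.011 with an estimated correlation, and 0.051 without replicate 3 of the 2-day PLIN2 siRNA group). ABCA1, a cholesterol exporter, rose by 1.60. Of 29 interferon-induced genes, 28 fell, also adjusted over the list alone (adjusted p = 0.16 with an estimated correlation), with MX1 at -5.87 and IFIT1 at -4.40. Of 28 inflammation genes, 21 fell and 3 rose, with 22 and 3 adjusted over the list alone (adjusted p = 0.011 with an estimated correlation); TNFAIP3 and CXCL1 were at -2.28 and -3.19. Of 35 cell cycle genes, 34 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.0027 with an estimated correlation), with CDK1 at 5.25. Mitochondrially encoded genes had 6 of 13 higher, also adjusted over the list alone (median 0.69; adjusted p = 0.6 with an estimated correlation), among them MT-CO3 at 0.68. The adjusted p of that list was 0.038, and 0.073, 0.052 and 0.05 without control replicate 3 at the end of the load or replicate 2 or 3 at 2 days. Without replicate 3 of the 2-day PLIN2 siRNA group all 13 rose (list adjusted p = 7.3e-06, and 0.28 with an estimated correlation). Markers of other cell types also moved. The collecting duct markers SCNN1A and AQP3 were at 0.68 and 0.65 and HSD11B2 at -1.26, the fibroblast markers DCN and THY1 were at 1.25 and -0.96, and the immune marker CD14 at 1.37. CD14 was the only call among the 3 immune markers tested, with CD68 at 0.1 (adjusted p = 0.66). In all, 3911 genes rose and 3915 fell, a total of 7826 that became 11140 without that library.

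The fifth comparison asked what the PLIN2 siRNA changed 2 days after the load. Cholesterol and fatty acid synthesis and the cell cycle were lower, and several proximal tubule genes were higher. Of 25 cholesterol genes, 24 fell and 1 was not called, also adjusted over the list alone (median -1.23; list adjusted p = 2.4e-21, and 0.01 with an estimated correlation). INSIG1, which holds SREBP in the ER, fell from 333 ± 6.29 to 60.5 ± 9.54 CPM. MSMO1 and FDFT1 fell (log2 fold changes -1.59 and -1.24). In fatty acid synthesis, 14 of 19 genes fell and 1 rose, with 17 and 1 adjusted over the list alone (adjusted p = 0.037 with an estimated correlation). SCD fell from 820 ± 8.26 to 246 ± 14.2 CPM, and FADS2 and FADS1 fell (log2 fold changes -1.88 and -1.06).

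Of 35 cell cycle genes, 28 fell and 7 were not called, with 30 adjusted over the list alone (median -0.59; adjusted p = 0.037 with an estimated correlation, and 0.15 without replicate 3 of this group). TYMS, CCNB1 and CCNB2 fell (log2 fold changes -1.09, -0.88 and -0.89). In the NRF2 list, 13 of 23 fell and 2 rose, with 15 and 2 adjusted over the list alone (adjusted p = 0.027 with an estimated correlation, and 0.15 without that library); TKT fell by 0.81. In the glycolysis and HIF list, 18 of 28 fell and 1 rose, with 20 and 2 adjusted over the list alone (adjusted p = 0.38 with an estimated correlation), with PFKFB3 at -0.98 and ALDOC at -1.35. In the tubule injury list, 10 of 23 fell and 3 rose, the same adjusted over the list alone (adjusted p = 0.064 with an estimated correlation); KRT19 and VIM were at -1.70 and -0.57. That list's adjusted p was 0.021, and 0.083 and 0.052 without replicate 1 or 2 of the PLIN2 siRNA group. The matrix list had 13 of 29 lower and 4 higher, with 15 and 4 adjusted over the list alone (adjusted p = 0.46 with an estimated correlation), with LOXL2 at -1.15 and ACTA2 at -0.77. Its adjusted p was 0.038, and 0.06, 0.071 and 0.057 without control replicate 2 or PLIN2 siRNA replicate 2 or 3. In lipid droplet coat and storage, 11 of 24 fell and 3 rose, the same adjusted over the list alone (adjusted p = 0.47 with an estimated correlation); CAV1, CAVIN1 and LPIN1 fell (log2 fold changes -0.87, -1.01 and -0.87). Its adjusted p was 0.021 with a median of -0.28, and 0.069 with a median of -0.11 and 7 genes higher without PLIN2 siRNA replicate 3. In this list 4 of 24 genes, CAVIN1 among them, hold in their 3' UTR the word GAGCCGC, which was more frequent in genes lower with this siRNA, as does LOXL2; the list's median was -0.17 without these 4.

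Of 32 proximal tubule genes, 13 rose and 1 fell, the same adjusted over the list alone (median 0.29; adjusted p = 0.065 with an estimated correlation, and 0.042 without replicate 3 of this group). PDZK1, a scaffold of apical transporters, rose by 1.20, SLC4A4, the basolateral bicarbonate transporter, by 0.97 and SLC3A1 by 0.63. Markers of other cell types also moved. The collecting duct markers SCNN1A, whose 3' UTR also holds GAGCCGC, and AQP3 were at -0.99 and -0.73 (adjusted p of AQP3 0.0037, and 0.079 when only the groups compared were fitted) and HSD11B2 at 1.35, and the fibroblast markers DCN and THY1 were at -0.62 and 0.64. Of 21 PPAR targets, 9 rose and 2 fell, with 10 and 2 adjusted over the list alone (adjusted p = 0.04 with an estimated correlation, and 0.15 without replicate 3, when 13 rose and 4 fell). CPT1A rose from 37 ± 1.25 to 83.3 ± 2.07 CPM, and PDK4 rose by 1.09. DDC, which makes dopamine, rose from 1.01 ± 0.212 to 4.36 ± 0.874 CPM, and FOXJ1, a regulator of motile cilia, from 6.49 ± 0.368 to 26.9 ± 8.43 CPM. All 13 mitochondrially encoded genes rose, also adjusted over the list alone (median 1.18; adjusted p = 0.6 with an estimated correlation). Their median was 0.38 without replicate 3, the library with 19.76% mitochondrial reads, and all 13 were still called. The other 2 siRNA libraries also lay outside the other groups, with 8.51% mitochondrial reads each and GC contents of 50.89% and 50.87%, against 51.41% to 51.47% in the controls. In all, 3218 genes rose and 3161 fell; 8278 genes were called without replicate 3, and 2189 genes were called when only the 6 libraries compared were fitted, against 6379 with all 15.

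**Figure D3:**
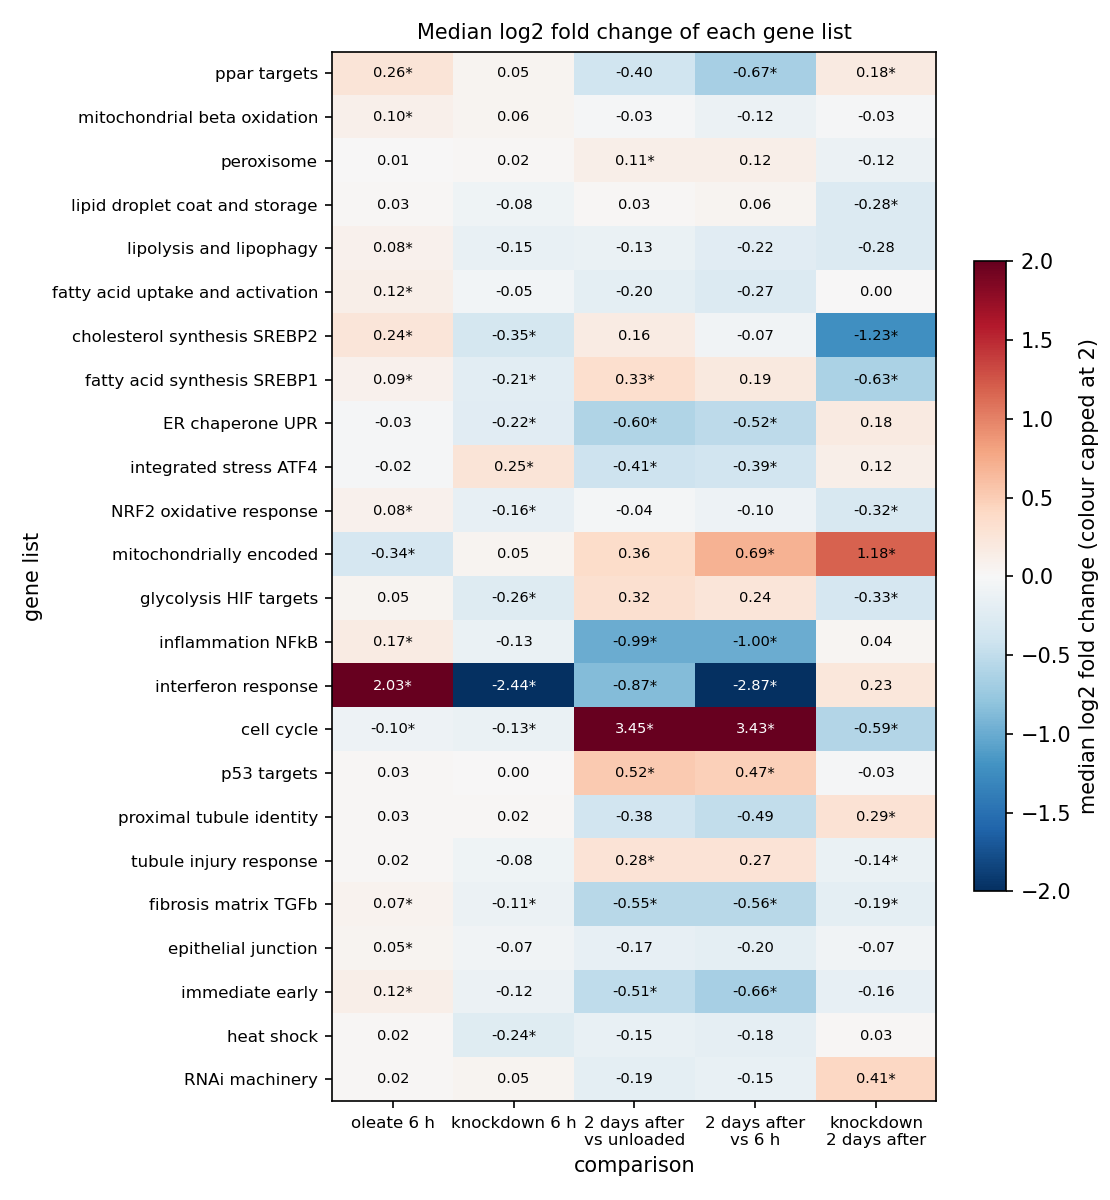
Median log2 fold change of 24 gene lists (vertical axis) in the 5 comparisons of 2 groups (horizontal axis), with colour capped at 2 in either direction and an asterisk where the list passed the preset-correlation test at an adjusted p of 0.05. The cholesterol list has a median of -0.35 with the PLIN2 siRNA at 6 h and -1.23 at 2 days.

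The sixth comparison tested whether the effect of the PLIN2 siRNA differed between 2 days and 6 h. The fall of cholesterol genes was larger at 2 days. Of 25 genes, 21 had a more negative effect at 2 days, with 24 adjusted over the list alone (median difference -0.74; adjusted p = 0.0069 with an estimated correlation). INSIG1 differed by -2.30 and MSMO1 by -1.37. Interferon-induced genes differed the other way, with 23 of 29 higher and 25 adjusted over the list alone (median 2.80; adjusted p = 0.069 with an estimated correlation). In the interferon list 5 genes rose and 2 fell with the siRNA at 2 days (median 0.23, list adjusted p = 0.44), and 3 rose and 3 fell without replicate 3 of the siRNA group (median 0.09). CPT1A differed by 0.94. Of markers of other cell types, SCNN1A differed by -0.71 (adjusted p = 0.0038, and -0.36 and no longer called with gene length as an offset) and DCN by -0.65 (adjusted p = 0.002), and HSD11B2 by 1.43 (adjusted p = 0.00015). THY1 differed by 0.43 (adjusted p = 0.038), a call lost in 14 of 22 other settings, stricter thresholds not counted, among them those without 1 library except control replicate 1 at the end of the load and replicate 3 of the 2-day PLIN2 siRNA group. The difference was called for 801 genes upwards and 782 downwards. The total of 1583 became 4911 without replicate 3 of the 2-day PLIN2 siRNA group, and 2400 and 2323 without its replicates 1 and 2. It was 944, 945 and 844 without control replicate 1, 2 or 3 at the end of the load, and 861, 939 and 876 without those of the PLIN2 siRNA. It was 881, 902 and 950 without control replicate 1, 2 or 3 at 2 days.

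Genes called with the PLIN2 siRNA at both times mostly went the same way. The comparisons at 6 h and at 2 days share no library. Genes lower at both times numbered 687, against 185 for independent lists, and genes higher at both times 445, against 119. Genes that moved in opposite directions numbered 16 and 37, against 117 and 189. Log2 fold changes correlated across 11281 genes at r = 0.49, where genes are not independent replicates. Of the 191 genes that oleate raised, 99 fell with the PLIN2 siRNA at 6 h, against 11.2 for independent lists, and 13 rose, against 7.06. Among these 99 were 27 genes of the interferon list. For that list, a handling difference of the control oleate samples cannot be told apart from the treatment. Of the 85 that oleate lowered, 21 rose, against 3.14, and 11 fell, against 4.99. These comparisons share the control oleate libraries. Groups simulated with no changed gene gave a mean of 0.01 genes in opposite directions and at most 1. With no changed gene to call, that count cannot show how much shared libraries add to an overlap of changed genes. The correlation was -0.34, with -0.49 simulated, and the covariance was -0.0136, with -0.00846 simulated. The simulated spread, here and in the next pair, came from all 15 libraries. These include replicate 3 of the 2-day PLIN2 siRNA group, which is in neither pair. The simulated values may therefore be larger in size than shared libraries alone would give. Of the genes that oleate raised, 114 were below the unloaded level 2 days later, against 38.4, and 23 above it, against 38.8. Of those that oleate lowered, 49 were above it, against 17.3, and 22 below it, against 17.1. The correlation there was -0.17, with 0.52 simulated, and the covariance was -0.017, with 0.00926 simulated. Shared unloaded libraries push fold changes the same way in this pair, whereas the excess was in opposite directions. The 3 shared oleate libraries of the former pair cannot be split into parts of at least 2, so a part of its excess in opposite directions may come from them. Without replicate 3 of the 2-day PLIN2 siRNA group, more genes were called and the overlaps grew. Genes lower and higher with the siRNA at both times then numbered 2124 and 1595, against 798 and 576 for independent lists, and 229 and 172 moved in opposite directions, against 678 and 678. Of the genes that oleate raised, 507 then fell with the siRNA, against 181, and 157 rose, against 153; of those it lowered, 213 rose, against 118, and 160 fell, against 139. Of the genes that oleate raised, 547 were then below the unloaded level 2 days later, against 299, and 276 above it, against 292. Of those it lowered, 332 were above it, against 225, and 303 below it, against 230.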

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

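The tests of replicate 3 of the 2-day PLIN2 siRNA group and those of the interferon genes, except the one of depth, were chosen only after the result was seen.

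The effect of the PLIN2 siRNA differed between 2 days and 6 h for 1583 genes, by a test of the difference itself. Among lists, the median difference was -0.74 for cholesterol synthesis (adjusted p = 0.0069 with an estimated correlation). It was -0.56 for fatty acid synthesis (0.054 with an estimated correlation), -0.53 for the cell cycle (0.059), -0.20 for the NRF2 list (0.054), -0.19 for peroxisomes (0.054), -0.25 for lipid droplets (0.45) and -0.15 for nuclear oxidative phosphorylation genes (0.45). It was 2.80 for interferon-induced genes (0.069), 0.35 for ER chaperones (0.11), 0.30 for proximal tubule genes (0.086), 0.16 for RNA interference genes (0.096) and 1.13 for mitochondrially encoded genes (0.51). Without replicate 3 of the 2-day PLIN2 siRNA group the mitochondrially encoded median was 0.31 and that of lipid droplets -0.15. In that setting the adjusted p with an estimated correlation was 0.034 for cholesterol and fatty acid synthesis, 0.047 for proximal tubule genes and 0.058 for peroxisomes. It was 0.22 for interferon-induced genes, the cell cycle, the NRF2 list, lipid droplets and RNA interference genes. For ER chaperones and nuclear oxidative phosphorylation it was 0.36, and for mitochondrially encoded genes 0.4.

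Among the fixed genes, the log2 effect of the siRNA differed by 0.94 for CPT1A, -0.69 for HMGCS1, -0.98 for SCD and 0.55 for DDIT3. It differed by 0.90 for PDK4, whose call was lost in 9 of 22 other settings (stricter thresholds not counted here and below), and by -1.87 for CIDEC, lost in 12 of 21. It differed by 0.48 for HSPA5, lost in 8 of 22, and by 1.38 for LRP2, lost in 7 of 21. In a further setting, with gene length as an offset, the LRP2 value was reversed, at -0.12.

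Other assignments of the siRNA within each time were drawn for the difference of effects: 5 of 100, the real one included, gave as many genes, with 1583 genes in the real assignment and at most 2880 in another. All 4 of the others as large kept the siRNA groups whole at 2 days, and so kept the siRNA effect of that time, while those mixed at both times, at most 1 gene, had the siRNA effect in their spread. These assignments therefore do not show whether chance is excluded. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In the order of the report, 1 split gave as many genes in each: the real ones gave 276, 1707, 7218, 7826 and 6379 genes, and the highest others 1, 0, 0, 0 and 0.

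Replicate 3 of the 2-day PLIN2 siRNA group stood apart, with 19.76% mitochondrial reads and a correlation of 0.958 and 0.965 with the other 2 libraries, which correlated at 0.988. A wrong label from another group is argued against by its PLIN2 level of 12.2 TPM, below every library of the other 4 groups, and immune cells by a median of 0 reads over the 10 immune markers in this library, of which 7, PTPRC and TYROBP among them, had at most 3 reads in any library, although CD68 was at 163 CPM against 111 and the sum was 1.34 times that of the higher of the other 2, with CD14 at 3.57 against 4.94. Cells of other types stay open: the sum of their markers was 0.71 times that of the higher of the other 2 libraries, but THY1, SCNN1A and DCN, at 135, 68.3 and 92.2 CPM here, had means of 191, 97.2 and 127 there, which would hide a small share, and loop and distal tubule markers summed to 5.33 CPM against 5.08 and 4.79. A trend over GC content took 49% of the variance of its deviation, which leaves GC bias open for nuclear genes, while GC bias alone is argued against for the mitochondrially encoded genes, whose median deviation was 1.68, above the 95th percentile of 0.87 of nuclear genes in the same range of GC content. RNA quality, which may differ, and biological explanations were not tested.

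Interferon-induced genes were highest in the control siRNA cells after 6 h of oleate, with a list mean log2 CPM of 4.52. The mean was 2.72 in unloaded cells and 2.38 in PLIN2 siRNA cells after 6 h of oleate. At 2 days it was lower still, at 1.67 with the control siRNA and 1.86 with the PLIN2 siRNA. With every library thinned to the smallest total, 96.7% of the difference from unloaded cells stayed, which argues against depth, and the lowest of the 3 libraries lay 1.18 above the highest of the other groups in list mean log2 CPM, which argues against a single library. As the source of the rise above unloaded cells, the control siRNA by itself is argued against by a difference of 1.81. Both groups had that siRNA. A rise with oleate whatever the siRNA is argued against by a difference of 2.14 from PLIN2 siRNA cells with the same oleate. A rise caused by oleate that the PLIN2 siRNA lowered would give the same difference, so it stays open. A handling difference of these 3 samples cannot be told apart from the treatment, since 0 other groups had the control siRNA with oleate and were collected at the end of the load. A response to oleate that needs PLIN2, or an effect of the PLIN2 siRNA on other genes, may account for the pattern. These hypotheses were not tested. Of the 29 genes, 0 hold in their 3' UTR the word GAGCCGC, which was more frequent in genes lower with this siRNA. That count covers list members alone and not genes that act on them, so it does not weigh against an effect on other genes.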

How the results depend on the processing

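The setting without replicate 3 of the 2-day PLIN2 siRNA group was chosen only after the result was seen. Values below follow the order oleate at 6 h, PLIN2 siRNA at 6 h, 2 days against unloaded, 2 days against 6 h, PLIN2 siRNA at 2 days, and the difference of siRNA effects. For changes of more than 1.5 times in the number of called genes, the cause was not tested, except where given below or where the setting itself calls fewer genes. A test against a fold change of 1.5 gave 20, 78, 1742, 2193, 598 and 60 genes, and the PLIN2 fall of -0.42 at 2 days against unloaded cells was no longer called. An adjusted p of 0.01 gave 123, 832, 3731 and 509 for oleate, for the siRNA at each time and for the difference. Fitting only the groups compared gave 1190 for oleate and 6079 and 2189 for the siRNA at 6 h and 2 days. Leaving out replicate 3 of the 2-day PLIN2 siRNA group gave 1792 for oleate and 6010 for the siRNA at 6 h. Both settings keep that library out of the spread of these comparisons, so its spread lowered their counts in the main fit. The siRNA comparison at 2 days holds that library, and its count was lower when fitted alone than with the spread shared by all groups (6379). DESeq2 gave 526 for oleate. No filter gave 1132 for the siRNA at 6 h and 1010 for the difference, for which gene length as an offset gave 997. Leaving out 1 library gave 118 to 1792 for oleate, 961 to 6010 for the siRNA at 6 h and 844 to 4911 for the difference. RLE size factors, limma-voom and library totals alone kept all 6 counts within 1.5 times.

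Gene lists called with an estimated correlation numbered 5, 0, 2, 3, 6 and 1. Fry called 19 and 21 lists for the siRNA at 6 h and 2 days and 28 and 25 for 2 days against unloaded and against 6 h, and leaving out 1 library gave 9 to 13 lists for oleate. At an adjusted p of 0.01, genes that oleate raised or lowered overlapped with the PLIN2 siRNA at 6 h in 3 (both higher), 4 (both lower), 54 (higher, lower) and 5 (lower, higher) genes, and with 2 days against unloaded in 9, 6, 46 and 16. The PLIN2 siRNA at 6 h and at 2 days overlapped in 181, 375, 4 and 9. Without replicate 3 of the 2-day PLIN2 siRNA group these were 157, 160, 507 and 213, then 276, 303, 547 and 332, then 1595, 2124, 229 and 172. Of 263 called results of named genes, 142 kept their direction and call in all settings run, and 83 lost the call only at an adjusted p of 0.01 or against a fold change of 1.5. The LRP2 difference of siRNA effects was -0.12 with gene length as an offset. Replicate numbers did not pair the samples (correlations of deviations from -0.06 to 0.06 over 30 pairs), and a replicate block gave 214, 1450, 6968, 7554, 6062 and 1250 genes. Depth limits genes of few reads: 42822 were not tested.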

Other observations

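The test of words in 3' UTRs was planned; none reported here was chosen only after the result was seen, except the values without replicate 3 of the 2-day PLIN2 siRNA group.

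Genes of the RNA interference machinery were higher with the PLIN2 siRNA at 2 days. Of 12 genes, 7 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.037 with an estimated correlation, and 0.15 without replicate 3 of the group). DICER1, which cuts small RNA precursors, rose by 0.87, and AGO4 by 0.80, or 0.39 and no longer called with gene length as an offset. Among peroxisome genes, 9 of 29 rose and 1 fell in control cells at 2 days against unloaded cells, the same adjusted over the list alone (adjusted p = 0.039, and 0.12 with an estimated correlation). Without replicate 3 of the 2-day PLIN2 siRNA group 13 rose and 5 fell. That list's adjusted p was 0.053 without unloaded replicate 2, 0.056 without 2-day replicate 2 and 0.051 with a replicate block. AMACR, a racemase of branched fatty acids, rose by 2.30. Of 9 gluconeogenesis genes, 4 rose and 1 fell in that comparison, with 5 and 1 adjusted over the list alone (list adjusted p = 0.24). PCK1 was at 4.24, and from 3.83 to 4.66 in 16 other settings. PCK1 did not pass the filter of 5 CPM in 3 libraries, so its level was low. Its standard error was large, at 0.6 without replicate 3 of the 2-day PLIN2 siRNA group.

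A word of 7 bases was more frequent in the 3' UTRs of genes that fell with the PLIN2 siRNA than in those of all genes, although most of these genes lacked it. Of 16181 words of 7 bases tested over 10729 genes, GAGCCGC had the lowest z at 6 h (-13.41), and at 2 days, in libraries not shared, its z was -15.66 without replicate 3 and -14.43 with it. Its z was -0.75 for oleate. The word was in 14.1% of the 660 genes with a UTR that were lower at both times, 1.5% of those higher at both and 3.8% of all 13953 genes with a UTR, and it lies in the PLIN2 coding sequence on chromosome 9, 19126117 to 19126123, in exon 3 of 8, although 25% of words lie in PLIN2 transcripts. Seed-matched silencing of other genes by the siRNA, whose sequence is not given in the sources used here, may account for part of these falls. Of 25 cholesterol genes, 1 holds the word, and without that gene the list's median was -0.35 at 6 h and -1.21 at 2 days. Leaving out 1 gene can hardly move a median, so these medians do not show whether silencing of genes outside the list lowered it. Without its members that hold the word, the lipid droplet list's median at 2 days was -0.17, against -0.28 with them. Of the genes named here, CAVIN1, CIDEC, LOXL2 and SCNN1A hold the word.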
